A study of Mus musculus with 7 samples.

How the data were processed

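Cortices of 7 mouse embryos were profiled by single-cell RNA sequencing on the Seq-Well platform, 1 library per embryo. The labels give 4 embryos with the Cre and floxed Ash1l (replicates 10, 11, 12 and 17) and 3 with floxed Ash1l alone (replicates 14, 15 and 16), all of 1 litter. The embryo was the replicate in every test, and the labels give neither sex nor library batch. Genotype came from the titles and characteristics of the samples.

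The authors deposited 1 table of whole-number counts per library, with gene symbols in 1 dimension and bead barcodes in the other. Per the labels' protocols, the assay counts UMIs; the values are whole numbers with different totals per library and were not normalised. Alignment used STAR with the mm10 build, per the submitters' processing notes. The aligner's version, the gene annotation, the rule for keeping barcodes and the collapsing of UMIs are not given in the sources used here. Gene coordinates were taken from the GENCODE annotation of mm10 by gene symbol and may differ from the annotation that the counts were made with. How genes that overlap or share sequence were counted is likewise not given, so haemoglobin paralogs and Gm26924 are uncertain as single genes.

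The tables held 50191 barcodes, 23413 gene symbols in their union and 62753750 UMIs, from 7083225 to 11859209 UMIs per library. No row was without a gene name. No pair of libraries agreed within sampling noise, with a chi-square per gene between pairs from 6.38 to 41.7. Barcodes with at least 500 detected genes and a mitochondrial share of at most 10% were kept. Scrublet, in scanpy 1.11.5, was run per library with an expected doublet rate of 5% and marked 13 cells (0.0565%), which were left out. A caller that marks so few cells did not work, so doublets were in effect not removed. In all 22992 cells entered the analysis.

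Counts were scaled to 10000 per cell and log-transformed. From 2000 variable genes, chosen within embryos without mitochondrial, ribosomal, haemoglobin and sex-linked genes, 30 principal components were computed. A graph of 15 nearest neighbours was divided with the Leiden method at resolution 1.0 (seed 1), which gave 23 clusters. Clusters were named by hand from fixed marker lists. A total of 13574 cells fell in 11 named classes, and 8 clusters with 9418 cells (41.0%) stayed unnamed. The names are of this clustering and carry limits. Cluster 16, counted as radial glia, was led by cell cycle genes and had 0 radial glia markers among its top 10 genes. Cluster 14, the striatal neurons, had 2 striatal and 2 interneuron markers there. Cluster 7, counted as deep-layer neurons, had 1 deep-layer marker, Ldb2, there. The mean log2 fold change of deep-layer markers against all other cells was 0.87 in cluster 7 and 2.12 in cluster 10. Cluster 18 had 5 interneuron markers among its top 10 genes and stayed unnamed. Its mean log2 fold change against all other cells was 1.64 for interneuron markers. It was 0.057 for upper-layer and −0.096 for migrating excitatory neuron markers. In the same order these 3 values were 3.22, −1.17 and −1.56 in interneuron cluster 9. In interneuron cluster 11 they were 1.79, −0.56 and −0.22. The median UMIs of a cell, relative to its library's median, were 1.61 in cluster 18, 0.84 in cluster 9 and 0.98 in cluster 11. Doublets of interneurons with other cells were not excluded in cluster 18. With a minimum of 300 detected genes, 82.7% of cells kept their class.

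For each comparison, raw UMIs were summed per embryo over all kept cells or over the cells of a class. Glutamatergic neurons joined the migrating excitatory, upper-layer and deep-layer neurons, and dorsal progenitors joined radial glia and intermediate progenitors. An embryo needed at least 20 cells of a class. The sums held 5316785 to 9460628 UMIs per embryo for all cells, 1820951 to 3497114 for glutamatergic neurons, 1007081 to 1760334 for upper-layer neurons, 237616 to 967250 for deep-layer neurons, 589015 to 1106189 for dorsal progenitors and 237733 to 412921 for interneurons. The quasi-likelihood test of edgeR with TMM normalisation and filterByExpr was the main test, two-sided, with a Benjamini-Hochberg adjusted p under 0.05. Counts at an unadjusted p under 0.05 are given in places. Chance alone puts a share of about 0.05 of tested genes or lists there, so such counts by themselves show no difference. CPM values are UMI counts scaled to a common library total after normalisation. The difference of the genotype effect between glutamatergic neurons and interneurons was tested in edgeR with the embryo as a fixed term.

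Gene lists, 32 in number, were tested with camera from limma at a preset correlation of 0.01 wherever at least 5 members were measured. Of the listed genes 8 were matched through an older symbol and 9 had no row. Camera with an estimated correlation and the rotation test fry were alternatives. Shares of cells were compared by an exact permutation test over the 35 splits of 7 embryos into 4 and 3. Cycling calls used S and G2/M scores after thinning each cell to 500 UMIs.

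The tests, cell filters, marker and gene lists, most alternative settings and the rule for naming genes were fixed before the data were examined. Genes named were, per comparison, up to 10 higher and 10 lower genes of smallest p past the threshold, filled where fewer than 10 passed with the next genes up to 5 per direction and given as not passing. Members of a list that passed over all genes or adjusted over the list alone, Ash1l and Emx1 were added. Spr in interneurons, and Spr, Npy and Fos in the comparison of classes, were named after their values were seen. List members that passed adjusted over the list alone are given in part, as examples. The values of 1 gene named by smallest p are not reported here.

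The tests were tested on simulated data, drawn from the means, dispersions and library sizes of these samples with 200 genes changed. Of genes changed 2-fold, edgeR recovered 53 of 67 in all cells, 48 of 67 in glutamatergic neurons, 52 of 67 in upper-layer neurons, 41 of 67 in deep-layer neurons, 44 of 67 in dorsal progenitors and 44 of 67 in interneurons. In the comparison of classes 15 of 67 were recovered. Of genes changed 1.5-fold, between 10 and 28 of 67 were recovered in the 6 groupings and 3 of 67 in the comparison of classes. False calls made up 10.8% of calls in glutamatergic neurons, 7.19% in all cells, 6.40% in dorsal progenitors and under 5% in the other comparisons. Each simulated gene was drawn independently, without differences between embryos shared by many genes. These rates therefore do not cover such structure in the real samples.

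Alternatives were size factors by relative log expression, DESeq2, voom with quality weights, other filters on genes and cells, other cluster resolutions, thinned cells, Xist as a covariate and leaving out each embryo in turn. Alternatives added after seeing the data were leaving out control 16 and mutant 17 together, leaving out the top 5% of doublet scores, adding or leaving out single unnamed clusters, and testing each cluster of the upper-layer and deep-layer classes alone. Software was Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.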

Results

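Single-cell RNA profiles were collected from the cortices of 7 mouse embryos of 1 litter at E18.5. In 4 mutant embryos both alleles of Ash1l carried loxP sites and a tamoxifen-dependent Cre recombinase was expressed from the Emx1 locus. The 3 control embryos carried the floxed alleles without the Cre. Ash1l encodes a histone H3 lysine methyltransferase, and Emx1 is expressed in the dorsal telencephalic progenitors that give rise to the glutamatergic neurons of the cortex. The dam received tamoxifen (100 mg/kg) at E10.5. Each embryo gave 1 Seq-Well library, in which cells are captured with barcoded beads in an array of small wells and transcripts are counted by unique molecular identifiers (UMIs).

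The control libraries (replicates 14, 15 and 16) held 8481526, 11228661 and 11859209 UMIs in total. The mutant libraries (replicates 10, 11, 12 and 17) held 7097700, 7083225, 8418077 and 8585352. After filtering, 2200, 3891 and 4285 control cells and 2108, 3153, 3714 and 3641 mutant cells were kept, 22992 in all. The median depth per cell was 1388 ± 227 UMIs in mutants (SD, n = 4) and 1638 ± 430 in controls (SD, n = 3; exact permutation p = 0.457, two-sided). The median mitochondrial share of UMIs was 3.83% ± 0.377 in mutants and 4.84% ± 0.787 in controls (exact permutation p = 0.0857). The smallest p that the 35 possible splits of 7 embryos allow is 0.0286. Libraries also differed in ways unrelated to genotype. The X-inactivation transcript Xist, in all cells summed, had a log2 CPM of 1.34 in control 15 and −0.61 in mutant 11. In the other embryos it was 9.62 to 10.4. Cluster 0, a group of cells led by haemoglobin, Gm10800 and Lars2 transcripts that was left unnamed, held 30.8% of cells in control 16 and 35.3% in mutant 17, against 10.3% to 15.7% in the other embryos.

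Ash1l itself was measured first in every embryo. In all cells summed its level was 158, 154, 165 and 125 CPM (UMI counts scaled to a common library total) in mutants 10, 11, 12 and 17, and 166, 217 and 207 CPM in controls 14, 15 and 16. This was 1.31-fold lower in mutants (log2 fold change −0.38, SE 0.12; edgeR adjusted p = 0.0107 over the 6 cell groupings and adjusted p = 0.335 over all genes). In glutamatergic neurons Ash1l was 1.38-fold lower (141 ± 13.2 against 194 ± 20.6 CPM), in upper-layer neurons 1.42-fold lower and in deep-layer neurons 1.66-fold lower (125 ± 21.5 against 202 ± 31.2 CPM; SD, n = 4 and 3). The edgeR p adjusted over the 6 groupings was 0.00187, 0.00125 and 4.9e-04, and all 4 mutants lay below all 3 controls in each. In dorsal progenitors (log2 fold change −0.29, SE 0.15; adjusted p = 0.0739) and GABAergic interneurons (−0.28, SE 0.18; adjusted p = 0.131) the groups overlapped. The genotype effect did not differ detectably between glutamatergic neurons and interneurons (difference −0.15 on the log2 scale, SE 0.16). The edgeR p was 0.373 unadjusted and 0.994 adjusted over all genes. Adjusted over all genes by edgeR, Ash1l passed in none of the 6 groupings; without control 14 it passed in deep-layer neurons (log2 fold change −0.84). The libraries are primed at poly(A) and the deleted part of the gene is not stated in the labels, so tags outside it would check nothing about recombination.

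**Figure D1:**
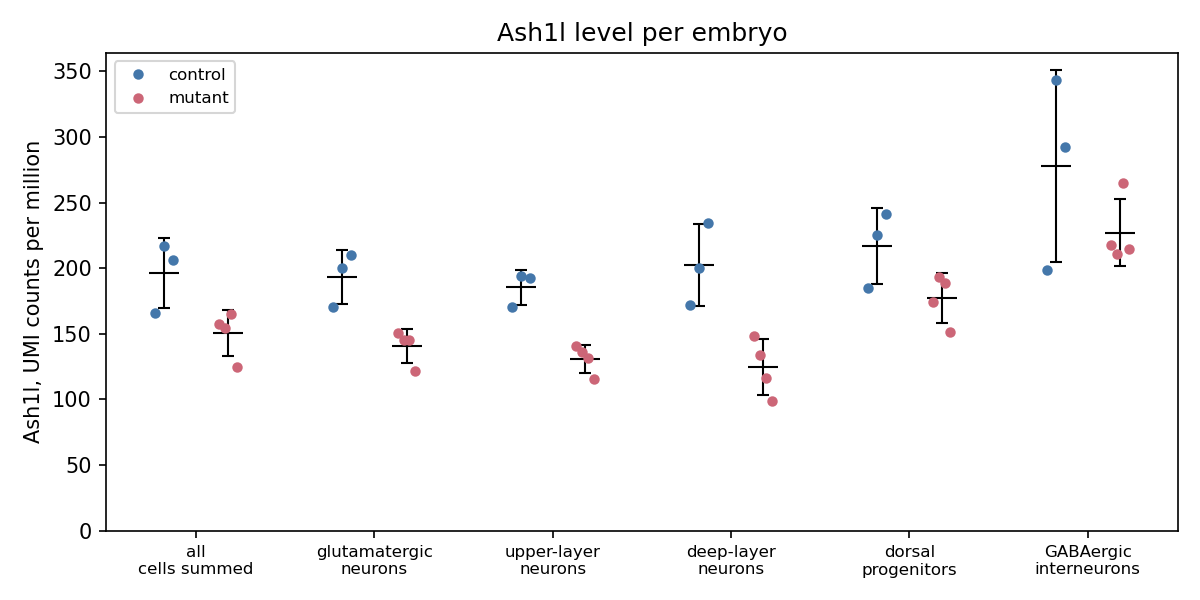
Ash1l level (CPM of UMIs, vertical axis) in each embryo, for all cells summed and for 5 cell groupings (horizontal axis). Points are embryos, and bars are the mean and SD of 3 controls and 4 mutants. In deep-layer neurons the mutants had a mean of 125 CPM and the controls 202 CPM.

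Summed over all cells, which asks how the cortex as a whole differed between genotypes, 2 genes were higher and 1 was lower in mutants among 12893 tested. Spr, the sepiapterin reductase of tetrahydrobiopterin synthesis, rose 2.49-fold (72.2 ± 14.0 against 29.1 ± 1.82 CPM; SD, n = 4 and 3; edgeR adjusted p = 0.00227). Esr1, the oestrogen receptor alpha gene, rose 10.7-fold from a low level (9.59 ± 3.47 against 0.891 ± 0.594 CPM; adjusted p = 0.00345). The CreERT2 protein contains part of the oestrogen receptor, and counts of that transgene cannot be separated from Esr1 in these tables. Npy, encoding neuropeptide Y, fell 2.54-fold (20.7 ± 3.13 against 52.7 ± 13.03 CPM; adjusted p = 0.00345). Spr lies on chromosome 6 at 85130176 to 85137766 (mm10, minus strand, protein coding), 49.7 kb from Emx1 at 85187438 to 85204462. Npy lies on the same chromosome, at 49822710 to 49829507. Emx1, whose locus carries the Cre, did not pass (log2 fold change 0.10, SE 0.14; edgeR adjusted p = 0.850).

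Among genes that did not pass over all genes, the smallest p-values belonged to Lmo3 (1.56-fold lower, adjusted p = 0.0510), Ppp1r3c (2.43-fold higher, adjusted p = 0.0660), the layer-restricted transcription factor gene Pou3f1 (1.61-fold lower, adjusted p = 0.0968) and Lrrn2 (1.63-fold lower, adjusted p = 0.108). Casp2 (1.47-fold higher), Gfap (2.59-fold higher) and Ncald (1.54-fold lower) followed with adjusted p of 0.172, 0.217 and 0.256.

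Of 30 gene lists tested in all cells with camera, 7 passed. Deep-layer identity genes fell as a group (17 of 18 members with a negative fold change, camera adjusted p = 0.00140; adjusted p = 0.617 with an estimated correlation). None passed over all genes and 3 passed adjusted over the list alone: Lmo3, Sox5 (1.38-fold lower) and Hs3st4 (1.81-fold lower). Deep-layer neurons made up 5.73% ± 1.89 of all cells in mutants and 8.22% ± 1.57 in controls. Upper-layer identity genes also fell (11 of 17 negative, camera adjusted p = 0.00661; adjusted p = 0.617 with an estimated correlation), with 4 members past the test adjusted over the list alone and 0 over all genes, including Pou3f1, Inhba (2.04-fold lower) and Rorb (1.45-fold lower). Synapse genes (28 of 39 negative, adjusted p = 0.00680) and ribosomal protein genes (60 of 78 negative, adjusted p = 0.00606) fell by the same test with no member past either threshold. For both the adjusted p was 0.858 with an estimated correlation. Heat shock and unfolded protein genes fell (14 of 17 negative, adjusted p = 0.00273; adjusted p = 0.617 with an estimated correlation), 3 of them adjusted over the list alone, including the chaperone genes Hspb1 (2.53-fold lower) and Hspa1b (1.46-fold lower), and 0 over all genes. Notch signalling genes rose (14 of 19 positive, adjusted p = 0.00680; adjusted p = 0.858 with an estimated correlation) with no member past either threshold.

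Meninges and choroid plexus genes, markers of cell types other than cortical neurons, rose beside these groups (6 of 7 positive, camera adjusted p = 0.00680, and 0.652 with an estimated correlation). The collagen genes Col1a1 (3.93 ± 3.99 against 0.615 ± 0.450 CPM), Col1a2 (10.1 ± 5.02 against 3.48 ± 1.15 CPM) and Col3a1 (10.6 ± 6.14 against 1.85 ± 1.40 CPM) passed adjusted over the list alone and none passed over all genes. The rotation test fry called 0 lists in one direction (3 at an unadjusted p under 0.05). By gene, other tools called more: DESeq2 called 21 genes, among them Spr, and gave no adjusted p for Esr1 and Npy, while voom with quality weights called 64. Without mutant 17, 26 genes passed, without control 16 it was 9 and without control 14 it was 5.

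**Figure D2:**
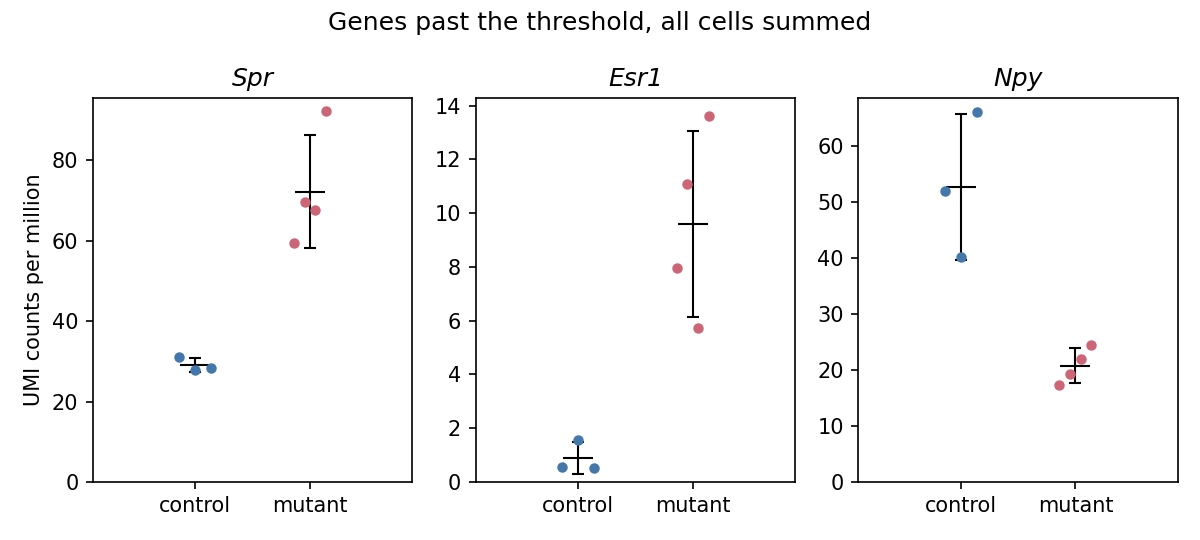
Levels of Spr, Esr1 and Npy (CPM of UMIs, vertical axes, from 0) with all cells of an embryo summed. Points are embryos, and bars are the mean and SD of 3 controls and 4 mutants; Spr averaged 72.2 CPM in mutants and 29.1 CPM in controls. Esr1 counts may include the CreERT2 transgene.

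Glutamatergic neurons descend from the progenitors in which the Cre acts. In this class 3 genes were higher and 8 lower in mutants among 10737 tested (edgeR adjusted p below the 0.05 threshold). Spr rose 2.49-fold (66.0 ± 14.7 against 26.8 ± 2.68 CPM; adjusted p = 0.00112), Esr1 8.83-fold (12.3 ± 3.98 against 1.37 ± 0.682 CPM; adjusted p = 0.00112) and Hif1an, a hydroxylase that inhibits the hypoxia factor HIF1A, 2.03-fold (36.2 ± 7.001 against 17.8 ± 3.65 CPM; adjusted p = 0.0489). Npy fell 3.20-fold (24.7 ± 11.6 against 78.3 ± 31.4 CPM; adjusted p = 0.00687). The imprinted long noncoding RNA Meg3 fell 1.81-fold (190 ± 26.8 against 343 ± 73.5 CPM; adjusted p = 0.0105), and the calcium sensor gene Ncald fell 1.92-fold (51.1 ± 9.87 against 98.8 ± 17.0 CPM; adjusted p = 0.0105).

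The RNA-binding splicing regulator Rbfox1 fell 1.52-fold in these neurons (180 ± 14.3 against 273 ± 7.76 CPM; adjusted p = 0.0402). The synaptic vesicle calcium sensor Syt1 fell 1.597-fold (116 ± 16.4 against 186 ± 27.6 CPM; adjusted p = 0.0489) and Lmo3 1.74-fold (72.1 ± 10.8 against 126 ± 27.9 CPM; adjusted p = 0.0433). Atf3, a stress-induced transcription factor, fell 3.23-fold (5.57 ± 1.11 against 18.02 ± 7.80 CPM; adjusted p = 0.0433), and Lmcd1 fell 7.74-fold at a low level (0.947 ± 1.31 against 7.66 ± 2.67 CPM; adjusted p = 0.0437).

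As groups, deep-layer identity genes (14 of 18 negative, camera adjusted p = 6.7e-04) and immediate early genes (15 of 20 negative, camera adjusted p = 0.0240) fell in glutamatergic neurons. Neither list passed with an estimated correlation (adjusted p = 0.948 with an estimated correlation for both), and fry called 0 lists (1 at an unadjusted p under 0.05). In the deep-layer list 6 members passed adjusted over the list alone and 1, Lmo3, over all genes. The others included the transcription factor genes Nfia (1.42-fold lower), Sox5 (1.42-fold lower) and Foxp2 (1.53-fold lower). Deep-layer neurons made up 16.5% ± 4.86 of this class in mutants and 21.8% ± 3.73 in controls (SD, n = 4 and 3; exact permutation p = 0.229), and migrating excitatory neurons 25.8% ± 5.71 and 20.3% ± 3.39 (exact permutation p = 0.200; adjusted p = 0.392 for both). Hs3st4, another of the 6, was at 83.4 CPM in mutant 17, where the deep-layer share was 22.8%, and at 35.3 to 50.6 CPM in the other mutants, where it was 11.1% to 16.5%. In the immediate early list 8 members fell and 2 rose adjusted over the list alone, and 1, Atf3, passed over all genes. Egr1 was 1.82-fold, Jun 1.42-fold and Fos 1.58-fold lower, while Arc (2.38-fold) and Fosb (1.49-fold) were higher.

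Of other lists, Npy (GABAergic programme) and Syt1 (synapse) passed over all genes, as given above, and further members passed adjusted over the list alone. Among p53 targets 4 of 15 fell, including Btg2 (1.55-fold), Bbc3 (1.59-fold) and Cdkn1a (2.01-fold). In the histone methylation list Ash1l and Psip1 (1.28-fold) fell and Kdm5c (1.44-fold) rose among 27. Of 17 upper-layer identity genes, Rorb (1.63-fold), Inhba (1.90-fold) and Pou3f1 (1.45-fold) fell and the netrin receptor gene Unc5d (1.38-fold) rose. None of these passed over all genes apart from the members named above, and none of the 3 lists passed camera (adjusted p = 0.154, 0.797 and 0.514). The number of genes called ranged from 3 without control 15 or mutant 11 and 4 without mutant 10 or 12 to 36 without control 14 and 99 without mutant 17. DESeq2 called 34 genes and shared 6 with the 11. It gave no adjusted p for Esr1 and did not call Npy; the calls of Syt1, Hif1an and Atf3 were lost under 15 of 22, 14 of 21 and 12 of 20 alternatives. Lmo3 lost its call under 9 of 22, Rbfox1 under 8 of 22, Lmcd1 under 5 of 16, Ncald under 4 of 22, Npy under 3 of 22 and Meg3 under 2 of 22.

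In upper-layer neurons, the callosal and intracortical part of that class, 3 genes were higher and 2 lower in mutants among 9472 tested. Spr rose 2.39-fold (62.8 ± 14.6 against 26.4 ± 1.58 CPM; edgeR adjusted p = 0.00358), and Esr1 stood at 14.1 ± 5.62 CPM in mutants and 0.402 ± 0.697 CPM in controls (adjusted p = 4.2e-04), with 2 of the 3 controls at 0. Islr2, a membrane protein with leucine-rich repeats, rose 1.62-fold (255 ± 19.3 against 157 ± 30.3 CPM; adjusted p = 0.0324). Ncald fell 1.82-fold (69.6 ± 9.06 against 127 ± 29.4 CPM; adjusted p = 0.0306) and Rbfox1 1.57-fold (191 ± 17.1 against 299 ± 25.5 CPM; adjusted p = 0.0306). Hist1h2bc (2.45-fold higher), Mfap3 (1.76-fold higher), Syt1 (1.57-fold lower) and Gucy1a3 (1.53-fold lower) came next, each with an adjusted p of 0.0555, and Arhgap29 (2.27-fold lower) followed at 0.0649. The class joins clusters 1 and 2, and cluster 2, of which Gucy1a3 and Inhba are leading genes, held 42.3% ± 7.26 of it in mutants and 55.1% ± 3.04 in controls, without overlap (exact permutation p = 0.0571, adjusted p = 0.171). Within cluster 1 alone and cluster 2 alone, tests chosen after seeing the data, Gucy1a3 was 1.26-fold lower in each (edgeR adjusted p = 0.830 and 0.425) and Syt1 1.18-fold and 1.38-fold lower (adjusted p = 0.895 and 0.206). Spr passed in both clusters (2.39-fold and 2.30-fold higher, adjusted p = 0.0395 and 0.0235). Islr2 was 1.35-fold and 1.73-fold higher (adjusted p = 0.545 and 0.01798) and Rbfox1 1.42-fold and 1.59-fold lower (adjusted p = 0.421 and 0.0183). Ncald, tested in cluster 2, was 1.49-fold lower and did not pass (adjusted p = 0.206). The difference between the clusters was not tested. Over the alternatives Islr2 lost its call under 7 of 24, Ncald under 7 of 23 and Rbfox1 under 6 of 24.

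The erythroid list was the one that camera called in upper-layer neurons (adjusted p = 0.0249; adjusted p = 0.741 with an estimated correlation). Its 5 measured members, 4 haemoglobin genes and the haem synthesis gene Alas2, all rose adjusted over the list alone, and none passed over all genes. Hbb-bs was 2.00-fold (1182 ± 492 against 589 ± 377 CPM) and Hbb-bt 2.35-fold higher, transcripts of red blood cells rather than neurons. The rotation test fry called 0 lists, and with a coarser clustering (Leiden resolution 0.6) the direction of Hba-a1 and Hba-a2 turned. In cluster 1 alone the log2 fold change of the 4 haemoglobin genes was −0.34 to −0.016, and in cluster 2 alone it was 1.27 to 1.83. Adjusted over the list alone, 7 of 18 immediate early genes fell and 2 rose (Junb 1.59-fold and Egr1 1.602-fold lower, Arc 2.91-fold higher), and 6 of 17 upper-layer identity genes fell and 1 rose (Inhba 2.04-fold, Rorb 1.77-fold and Pou3f1 1.49-fold lower, Unc5d 1.40-fold higher). None of these passed over all genes, and the camera adjusted p of the lists was 0.0701 and 0.164. In cluster 1 alone the immediate early list fell (14 of 15 negative, camera adjusted p = 3.0e-12; adjusted p = 0.141 with an estimated correlation), and in cluster 2 alone it did not pass (8 of 17 negative, adjusted p = 0.744). Heat shock genes (13 of 14 negative) and ribosomal protein genes (44 of 61 negative) fell with it in cluster 1, both with a camera adjusted p of 0.00940 (adjusted p = 0.346 and 0.866 with an estimated correlation). The intermediate progenitor list was also called there (5 of 9 negative, camera adjusted p = 0.0339; adjusted p = 0.767 with an estimated correlation). Fos, Egr1 and Jun were among the genes used for clustering, and the difference between the clusters was not tested. The upper-layer identity list passed in neither cluster alone (camera adjusted p = 0.852 and 0.161). Its mean log2 fold change was −0.028 in cluster 1 and −0.175 in cluster 2. Adjusted over the list alone, 1 of 15 and 5 of 17 members were lower there. In cluster 2 Inhba was 1.86-fold and Rorb 1.66-fold lower (edgeR adjusted p = 0.206 for both).

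Among the other lists in upper-layer neurons, 3 of 13 deep-layer identity genes fell adjusted over the list alone (Lmo3 2.14-fold, Nfia 1.499-fold, Ldb2 1.56-fold) and 2 of 17 Wnt signalling genes rose (Fzd9 2.30-fold, Lrp6 1.44-fold), none of them over all genes. The mitochondrial ribosomal RNA mt-Rnr1 fell 1.26-fold by the same adjustment. The number of genes called ranged from 2 without control 15 or mutant 11 and 3 without mutant 10 or 12 to 12, 40 and 52 without control 16, mutant 17 and control 14. DESeq2 called 25 genes and gave no adjusted p for Spr and Esr1. The erythroid call was lost without control 15, mutant 10 or mutant 11, where 0 lists passed camera.

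In deep-layer neurons, which project out of the cortex, 6 genes were higher and 1 was lower among 8610 tested. Spr rose 3.01-fold (81.4 ± 15.8 against 28.2 ± 4.97 CPM; edgeR adjusted p = 5.1e-04) and the neuropeptide gene Nts 2.00-fold (707 ± 306 against 358 ± 31.2 CPM; adjusted p = 0.0127). Tm9sf1 rose 5.14-fold (22.04 ± 11.6 against 4.78 ± 2.83 CPM; adjusted p = 0.0370). The remaining higher genes were Gm26924 (1.42-fold, adjusted p = 0.0366), the mitochondrial leucyl-tRNA synthetase gene Lars2 (1.88-fold, adjusted p = 0.0366) and Rpph1, the RNA component of ribonuclease P (5.79-fold, adjusted p = 0.0370). Npy fell 3.01-fold (67.8 ± 32.2 against 187 ± 87.7 CPM; adjusted p = 0.00127). In clusters 7 and 10 of the class, each tested alone after seeing the data, Npy was 4.31-fold (adjusted p = 1.8e-05) and 1.43-fold lower (adjusted p = 0.808), and Spr 3.73-fold (adjusted p = 2.2e-04) and 2.07-fold higher (adjusted p = 0.484). Nts was 2.02-fold and 2.12-fold higher there and passed in neither (adjusted p = 0.218 and 0.0761), and the difference between the clusters was not tested. Mutant and control embryos overlapped for Lars2, Rpph1 and Npy. Lars2 and Gm26924 were also among the 10 leading genes of the unnamed cluster 0, and their log2 fold changes were positive in all 6 groupings (0.82 to 0.95 and 0.39 to 0.51). Of these they passed over all genes in deep-layer neurons, and whether the change there differed from the other groupings was not tested. Rpph1 (1.45 to 2.53) and the ribosomal RNA n-R5-8s1 (1.32 to 1.59) were likewise positive in the 5 groupings where they were tested. Over the alternatives Spr lost its call under 2 of 23, Npy under 5 of 24, Gm26924 under 7 of 24, Nts and Lars2 under 8 of 24, Tm9sf1 under 5 of 12 and Rpph1 under 7 of 17.

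Deep-layer identity genes fell as a group in these neurons (13 of 17 negative, camera adjusted p = 0.00328; adjusted p = 0.339 with an estimated correlation). The rotation test fry also called the list (adjusted p = 0.0414). Of its members 6 passed adjusted over the list alone and none over all genes. Foxp2, a transcription factor of corticothalamic neurons, was 1.87-fold lower (48.0 ± 6.40 against 86.4 ± 3.23 CPM), Nfia 1.53-fold, Lmo3 1.39-fold and Nfib 1.26-fold lower. The class joins clusters 7 and 10, and cluster 10, led by Hs3st4, held 39.5% ± 2.51 of it in mutants and 45.2% ± 2.51 in controls, without overlap (exact permutation p = 0.0571, adjusted p = 0.171). In cluster 7 alone and cluster 10 alone, tests chosen after seeing the data, 13 of 17 and 13 of 16 members were negative and the list did not pass (camera adjusted p = 0.0813 and 0.0895; adjusted p = 0.922 and 0.633 with an estimated correlation). Foxp2 was 2.71-fold and 1.55-fold lower there (edgeR adjusted p = 0.347 and 0.579). Neurodevelopmental disorder genes fell as well (33 of 44 negative, camera adjusted p = 0.0156, fry adjusted p = 0.0414; adjusted p = 0.339 with an estimated correlation). In that list 3 members, Ash1l and Foxp2 among them, passed adjusted over the list alone and none over all genes. In clusters 7 and 10 alone 27 of 43 and 32 of 42 members of that list were negative (mean log2 fold change −0.126 and −0.148). The list did not pass there (camera adjusted p = 0.181 and 0.0754). DESeq2 called 2 genes, 0 genes passed in edgeR when only genes with a mean of at least 50 UMIs were tested (279 at an unadjusted p under 0.05; voom called 13 of all genes), and the count was 1 without control 16, 2 without control 15, 3 without mutant 10, 14 without mutant 12 and 18 without control 14. Neither list passed without mutant 17.

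Dorsal progenitors, the radial glia and intermediate progenitors in which Emx1 is active, had 3 higher genes and 0 lower ones by edgeR among 9752 tested (612 at an unadjusted p under 0.05). Ppp1r3c, a subunit that targets protein phosphatase 1 to glycogen, rose 2.79-fold (82.5 ± 13.3 against 29.6 ± 4.16 CPM; adjusted p = 0.00134). Spr rose 2.40-fold (93.9 ± 25.7 against 38.9 ± 12.7 CPM; adjusted p = 0.0333). Gfap, the glial fibrillary acidic protein gene of astrocytes and late radial glia, rose 2.52-fold (64.0 ± 19.5 against 25.6 ± 4.004 CPM; adjusted p = 0.0333). Cluster 5, a radial glia cluster with 2 astrocyte markers, Aldoc and Aldh1l1, among its 10 leading genes, held 56.8% ± 3.31 of the class in mutants and 50.6% ± 4.76 in controls (exact permutation p = 0.114, adjusted p = 0.274). Gfap was not tested within single clusters. DESeq2 also called 3 genes, all higher, and voom called 4, of which 1 was lower. Spr lost its call under 11 of 23 alternatives and Gfap under 10 of 22 (adjusted p up to 0.559 and 0.443), while Ppp1r3c lost none of 23.

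Below the threshold in progenitors lay Cryab (3.51-fold lower, adjusted p = 0.0811), Npy (4.13-fold lower, adjusted p = 0.0987), Cyr61 (1.74-fold lower, adjusted p = 0.0987), Crym (2.28-fold higher, adjusted p = 0.162), Ppp1r14b (1.67-fold lower, adjusted p = 0.162) and the Wnt antagonist gene Sfrp2 (2.06-fold lower, adjusted p = 0.181). The ribosomal RNA n-R5-8s1 was 2.74-fold higher (adjusted p = 0.162). Ribosomal protein genes (54 of 68 negative, camera adjusted p = 0.00130) and upper-layer identity genes (14 of 16 negative, adjusted p = 0.0450) fell as groups, with no member past either threshold. Their adjusted p was 0.909 and 0.655 with an estimated correlation, fry called 0 lists, and without mutant 12 camera called 0. All 10 astrocyte and oligodendrocyte precursor genes had a positive fold change (camera adjusted p = 0.0561), of which Gfap passed both adjusted over the list alone and over all genes. Without control 15 or mutant 11 the count was 1, and without control 14 or mutant 17 it was 6.

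GABAergic interneurons reach the cortex from ventral progenitors outside the Emx1 lineage and served as an internal comparison. Here 4 genes were higher and 2 lower in mutants among 6664 tested. The higher genes were all haemoglobins: Hba-a2 (5.65-fold, 344 ± 147 against 60.9 ± 52.4 CPM; edgeR adjusted p = 6.7e-04), Hba-a1 (5.58-fold, adjusted p = 0.00131), Hbb-bt (5.05-fold, adjusted p = 0.00366) and Hbb-bs (5.03-fold, adjusted p = 0.00513). Haemoglobin UMIs were detected in 11.5% of 797 mutant and 8.56% of 596 control interneurons, at median depths of 1208 and 1414 UMIs, and 40 mutant cells held 99.1% of them. The immediate early genes Fos (1.83-fold, 404 ± 51.6 against 740 ± 83.4 CPM; adjusted p = 0.00513) and Atf3 (4.79-fold, 12.1 ± 7.17 against 60.0 ± 26.8 CPM; adjusted p = 0.0166) fell. Gadd45b (3.54-fold lower, adjusted p = 0.0558), Cmpk1 (1.78-fold lower, adjusted p = 0.137), Phf23 (2.11-fold lower, adjusted p = 0.143) and Bmper (3.65-fold higher, adjusted p = 0.276) had the next smallest p-values in their directions and did not pass.

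The immediate early list fell in interneurons (13 of 15 negative, camera adjusted p = 5.5e-06, fry adjusted p = 0.0139; adjusted p = 0.0592 with an estimated correlation). Adjusted over the list alone 7 members fell and 1 rose, and 2, Fos and Atf3, passed over all genes. Junb was 1.87-fold, Dusp1 1.80-fold and Jun 1.49-fold lower, and Fosb was 1.43-fold higher. Heat shock genes (13 of 14 negative) and ribosomal protein genes (47 of 56 negative) also fell, both with a camera adjusted p of 0.0126 and no member past either threshold. Their adjusted p was 0.424 and 0.992 with an estimated correlation. Spr, not called here, was at 37.1 ± 8.97 CPM in mutants and 15.7 ± 10.47 CPM in controls (log2 fold change 1.19, SE 0.45; adjusted p = 0.583). At Leiden resolution 0.6 and with a minimum of 300 detected genes per cell, 0 genes passed in edgeR (635 and 598 at an unadjusted p under 0.05), while DESeq2 called 1 gene and voom 6. With DESeq2 the haemoglobin genes had an adjusted p of 0.997. Over the alternatives Hba-a2, Hba-a1, Hbb-bt and Hbb-bs lost their calls under 4, 5, 6 and 8 of 23, Fos under 8 of 23 and Atf3 under 8 of 19. The count was 1 without control 15, 2 without mutant 17 and 10 without control 14.

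The difference of the genotype effect between glutamatergic neurons and interneurons was tested directly, with the embryo as a fixed term. It passed for 5 genes: Hba-a2, Hbb-bs, Hba-a1 and Hbb-bt, with a lower effect in glutamatergic neurons (differences of −2.80, −2.51, −2.71 and −2.19 on the log2 scale; edgeR adjusted p of 1.7e-06, 1.7e-06, 4.9e-06 and 1.0e-04), and the linker histone gene Hist1h1c, with a higher one (0.88, SE 0.15; adjusted p = 9.1e-04). Npy (−0.93, SE 0.28), Spr (0.09, SE 0.46) and Fos (0.27, SE 0.13) did not pass. Their edgeR p was 0.00167, 0.841 and 0.0513 unadjusted, and 0.594, 0.995 and 0.973 adjusted over all genes. On simulated data this test recovered 15 of 67 genes changed 2-fold, so a gene that did not pass is not shown to be alike in both classes. With voom and the embryo as a random effect, and also in edgeR without control 16 and mutant 17, 0 genes passed (379 and 494 at an unadjusted p under 0.05). By chance alone a share of about 0.05 of tested genes would have such a p.

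The share of cells in each of 11 named classes was compared to ask whether the make-up of the cortex differed. Upper-layer neurons made up 19.99% ± 2.85 of mutant and 21.9% ± 2.84 of control cells (SD, n = 4 and 3; exact permutation p = 0.371, two-sided). Deep-layer neurons made up 5.73% ± 1.89 and 8.22% ± 1.57 (exact permutation p = 0.143), the smallest p of the 11. Radial glia held 8.63% ± 2.44 and 7.39% ± 2.08 (exact permutation p = 0.486), intermediate progenitors 3.35% ± 1.05 and 3.37% ± 0.311, and migrating excitatory neurons 8.81% ± 1.64 and 7.67% ± 1.32. GABAergic interneurons held 6.52% ± 1.45 and 6.06% ± 1.74, Cajal-Retzius cells 1.89% ± 0.457 and 1.98% ± 0.515, and striatal neurons, which mark tissue next to the cortex, 2.53% ± 2.69 and 2.16% ± 0.808. Oligodendrocyte precursors, endothelial cells and microglia each stayed under 1% on average in both groups.

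The Benjamini-Hochberg adjusted p of the shares was 0.974 or more for all 11 classes, and 1 class alone at the smallest exact p that 35 splits allow could not pass after adjustment over 11 classes. The difference of deep-layer neurons was larger than either SD and did not pass before adjustment. It ranged from −3.25 (without mutant 17) to −1.63 (without control 15) percentage points when 1 embryo was left out (main −2.49). A share of 41.0% of cells lay in 8 clusters without a name, which were not compared. Of dorsal progenitors, 51.2% ± 3.73 in mutants and 50.2% ± 1.59 in controls scored as cycling after each cell was thinned to 500 UMIs (exact permutation p = 0.686). Not thinned, the shares were 48.1% ± 3.30 and 46.9% ± 4.12. By a UMI of Mki67 or Top2a the shares were 18.2% ± 2.47 and 18.7% ± 3.76 (exact permutation p = 0.886). Cluster 6, led by Top2a and Mki67, was unnamed and not counted among dorsal progenitors. With it added, a setting chosen after seeing the data, the cycling shares were 61.3% ± 3.59 and 59.9% ± 2.82 (exact permutation p = 0.657).

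**Figure D3:**
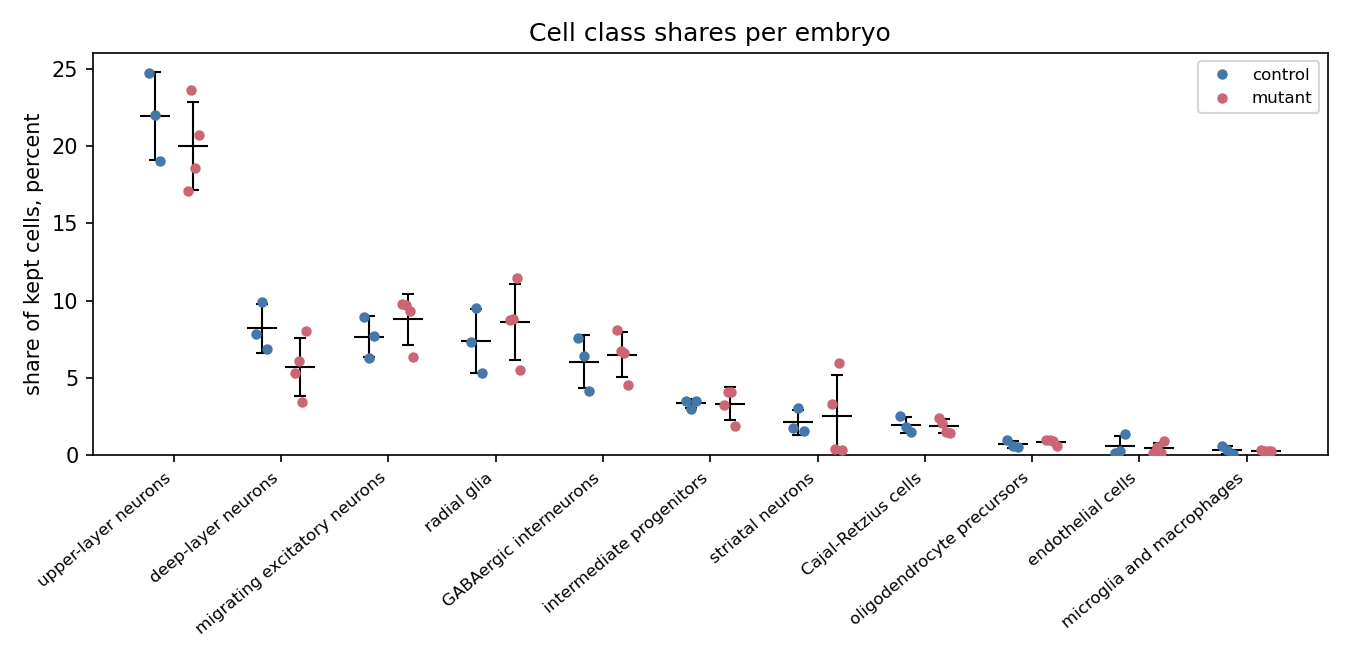
Share of kept cells (percent, vertical axis from 0) in each named cell class (horizontal axis). Points are embryos, and bars are the mean and SD of 3 controls and 4 mutants. Deep-layer neurons averaged 5.73% in mutants and 8.22% in controls, with overlapping embryos.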

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

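Of the tests in this part, the comparison of haemoglobin effects between classes and the test of cluster borders were chosen after the result was seen, and the reading of the latter was tightened later; the share of haemoglobin UMIs in the richest cells was set before its value was seen.

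In 6 of 56 sets of 4 mutant values, 1 embryo lay far from the others by Dixon's criterion; chance gives about 1 in 20. Mutant 17 was the embryo in 5 of the 6. Its share of migrating excitatory neurons was 6.37% (9.34% to 9.82% in the other mutants), and its Rbfox1 level in glutamatergic neurons was 200.8 CPM (171 to 176 in the others). Its Esr1 level in upper-layer neurons was 22.5 CPM (10.7 to 12.0 in the others), and its Ppp1r3c level in dorsal progenitors was 62.7 CPM (86.7 to 90.5 in the others). Its Hbb-bt level in interneurons was 1475 CPM (920 to 951 in the others). In mutant 12 the Ash1l level in interneurons was 265 CPM (211 to 218 in the others).

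The genotype effect differed between glutamatergic neurons and interneurons for 5 genes by edgeR. The log2 difference was −2.80 for Hba-a2 (SE 0.36), −2.51 for Hbb-bs (SE 0.33), −2.71 for Hba-a1 (SE 0.37), −2.19 for Hbb-bt (SE 0.34) and 0.88 for Hist1h1c (SE 0.15), with adjusted p from 1.7e-06 to 9.1e-04. Other splits of the embryos gave up to 8 genes, and 4 of the 35 splits gave at least 5, so chance was not excluded for this count.

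Haemoglobin transcripts were higher in mutant interneurons. Free RNA of blood cells would reach all classes of an embryo alike, but in edgeR the genotype effect differed between the classes for 4 of the 4 genes, with a mean log2 fold change of 2.41 in interneurons and −0.22 in glutamatergic neurons (0.98 in upper-layer and −1.25 in deep-layer neurons). The class difference rests on this test. With voom and the embryo as a random effect, or in edgeR without control 16 and mutant 17, 0 genes differed (379 and 494 at an unadjusted p under 0.05). The spread over cells does not depend on it. Mutant interneurons held 5738 haemoglobin UMIs, and 705 of 797 cells had none (545 of 596 in controls, with 1110 UMIs). Free RNA that reached cells alike would leave few without. These values, read after the results were seen, argue against free RNA as the main source in interneurons. A few cells captured together with a red blood cell are a candidate explanation: the richest 5% of mutant interneurons held 99.1% of the class's haemoglobin UMIs, and the richest 5% of control interneurons 98.1%, so the concentration was not particular to mutants. Cluster borders stay open, as does an effect of the genotype itself, which was not tested. At Leiden resolution 0.6 the mean log2 fold change was 1.61 (SE 0.45), above 1.21, which is 50% of the main value, by less than its error. By edgeR 0 genes passed at that resolution. With cluster 18 added to the interneurons, a setting chosen after seeing the data, 0 higher and 2 lower genes passed. The calls of all 4 haemoglobin genes were thus lost under both settings.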

How the results depend on the processing

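Alternatives that leave out control 16 and mutant 17, the top 5% of doublet scores or an unnamed cluster, or that add an unnamed cluster or take 1 cluster of a class alone, were chosen after seeing the data; the others were not. The named genes that passed gave 35 calls, a gene counting once in each grouping where it passed. Spr, Esr1 and Npy are among those counted more than once, and the groupings share cells. These calls had 755 values under alternatives, of which 561 kept the call, 194 lost it and 0 changed sign. For the counts, shares and Ash1l, 335 values kept their direction and call or stayed within 1.5 times the count, 113 counts moved, 26 values turned and 1 newly passed. Spr, Esr1 and Npy in all cells, Spr and Esr1 in glutamatergic and upper-layer neurons and Ppp1r3c in progenitors lost no call where an adjusted p was given; DESeq2 gave none for Esr1 in these 3 groupings, Npy in all cells and Spr in upper-layer neurons. Where a cause is not named below, the cause was not tested.

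With DESeq2 the number of genes was 21 in all cells (main 3), 34 in glutamatergic neurons (main 11), 25 in upper-layer neurons (main 5), 2 in deep-layer neurons (main 7) and 1 in interneurons (main 6). With voom and quality weights it was 64 in all cells, 143 in glutamatergic, 96 in upper-layer and 13 in deep-layer neurons. With no filter on low counts, which admits more genes, it was 164 in all cells, 150 in glutamatergic, 119 in upper-layer and 33 in deep-layer neurons, 26 in progenitors (main 3), 13 in interneurons and 9 in the comparison of classes (main 5). With genes of a mean of at least 50 UMIs it was 5 in glutamatergic neurons, 0 in deep-layer neurons by edgeR (279 at an unadjusted p under 0.05) and 1 in progenitors. With Xist as a covariate it was 6 in glutamatergic neurons, 11 in upper-layer neurons and 1 in progenitors. With cells thinned to at most 1000 UMIs it was 20 in glutamatergic and 19 in upper-layer neurons.

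At Leiden resolution 0.6 the number was 7 in glutamatergic neurons, 1 in progenitors and 0 in interneurons by edgeR (635 at an unadjusted p under 0.05), and at resolution 1.6 it was 22 in upper-layer neurons. With a minimum of 800 detected genes it was 5 in glutamatergic, 9 in upper-layer and 4 in deep-layer neurons. With a minimum of 300 it was 9 in upper-layer neurons, 1 in progenitors and 0 in interneurons by edgeR (598 at an unadjusted p under 0.05). With a mitochondrial share of at most 5% it was 5 in all cells, 7 in glutamatergic and 23 in upper-layer neurons. Without the top 5% of doublet scores it was 7 in glutamatergic and 8 in upper-layer neurons. With cluster 18 added it was 2 in interneurons, both lower in mutants. In upper-layer neurons it was 13 in cluster 1 alone, and in deep-layer neurons 4 in cluster 7 alone and 1 in cluster 10 alone, each fit holding fewer cells. Without control 16 and mutant 17 it was 35 in all cells, 43 in glutamatergic neurons, 51 in upper-layer neurons and 16 in progenitors, and 0 in the comparison of classes by edgeR (494 at an unadjusted p under 0.05). With voom and the embryo as a random effect, 0 genes passed in the comparison of classes (379 at an unadjusted p under 0.05).

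With an estimated correlation 0 gene lists passed camera in each of the 6 groupings (0, 0, 0, 2, 1 and 1 at an unadjusted p under 0.05; main 7 in all cells, 2 in glutamatergic, 1 in upper-layer and 2 in deep-layer neurons, 2 in progenitors and 3 in interneurons). With fry 0 passed in all cells, glutamatergic neurons, upper-layer neurons and progenitors (3, 1, 1 and 1 at an unadjusted p under 0.05), and 1 in interneurons. With clusters alone camera called 4 lists in cluster 1 and 0 in clusters 2, 7 and 10 (4, 5 and 3 at an unadjusted p under 0.05).

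Leaving out 1 embryo at a time, the number of genes ranged from 3 to 26 in all cells, 3 to 99 in glutamatergic neurons, 2 to 52 in upper-layer neurons, 1 to 18 in deep-layer neurons, 1 to 6 in progenitors, 1 to 10 in interneurons and 5 to 8 in the comparison of classes. The number of lists ranged from 7 to 11, 2 to 4, 0 to 4, 0 to 3, 0 to 6 and 2 to 5 in the 6 groupings in the same order. The highest gene counts came without mutant 17 in all cells and glutamatergic neurons and without control 14 in upper-layer and deep-layer neurons. The log2 fold change of Ash1l in deep-layer neurons ranged from −0.84 to −0.58 and passed over all genes without control 14 (edgeR adjusted p = 0.0125). For Ash1l in interneurons the range was −0.48 (without control 14) to −0.11 (without control 15). In glutamatergic neurons it was −0.54 to −0.40.

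No share passed the test, which 1 class alone could not pass after adjustment over 11, and the direction of small differences turned. The difference in percentage points, mutant minus control, for endothelial cells (main −0.150) was 0.0107 with a minimum of 300 detected genes and 0.0841 without control 16 and mutant 17. For intermediate progenitors (main −0.0138) it was 0.167 with a minimum of 300 genes, 0.0145 with a minimum of 800, 0.392 with a mitochondrial share of at most 5%, 0.116 as a share of glutamatergic-lineage cells and 0.562 without control 16 and mutant 17. For interneurons (main 0.454) it was −0.0248 with a minimum of 800 genes. On the logit scale the difference was 0.0288 for microglia and −0.425 for striatal neurons, against −0.0662 and 0.375 percentage points. The cycling share of progenitors (main 1.01) was −0.457 by a UMI of Mki67 or Top2a, −0.463 with a minimum of 300 genes and −1.71 with a minimum of 800. Leaving out 1 embryo at a time, the difference ranged from −0.307 to 0.195 for Cajal-Retzius cells, −0.490 to 1.22 for interneurons, −0.366 to 0.232 for endothelial cells, −0.271 to 0.472 for intermediate progenitors, −0.198 to 0.0509 for microglia, −0.783 to 1.09 for striatal neurons and −0.141 to 2.45 for the cycling share.

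Emx1 passed in no grouping, and its log2 fold change turned. For Emx1, all cells summed, it was −0.089 without control 16 and mutant 17 (main 0.098), and −0.078 to 0.18 without 1 embryo. For Emx1, upper-layer neurons, it was −0.020 with voom, −0.021 at resolution 1.6, −0.028 with a minimum of 800 genes, −0.12 in cluster 2 alone and −0.14 without control 16 and mutant 17 (main 0.052), and −0.14 to 0.17 without 1 embryo. For Emx1, deep-layer neurons, it was 0.22 with a mitochondrial share of at most 5% and 0.11 in cluster 10 alone (main −0.027), and −0.28 to 0.076 without 1 embryo. For Emx1, dorsal progenitors (main 0.14), it was −0.045 to 0.33 without 1 embryo. At Leiden resolution 0.6 the value for Hba-a1, upper-layer neurons, was −0.040 (main 0.94) and for Hba-a2, upper-layer neurons, −0.13 (main 0.75). In cluster 1 alone the values for upper-layer neurons were −0.24 for Hba-a1, −0.34 for Hba-a2, −0.27 for Hbb-bs (main 1.001), −0.016 for Hbb-bt (main 1.23) and 0.20 for Foxp1 (main −0.56). In cluster 7 alone Hs3st4, deep-layer neurons, was 0.24 (main −0.43). On simulated data at these depths, 44 of 67 genes changed 2-fold were recovered by edgeR in interneurons and 48 of 67 in glutamatergic neurons; of genes changed 1.5-fold it was 12 and 28 of 67, so changes of that size can be missed. No paired analysis was possible because the labels match no mutant embryo with a control embryo.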

Other observations

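Of the tests in this part, the splits of the embryos and the test of Spr in interneurons were chosen after the results were seen; the test of Esr1 against Emx1 and of genes near Emx1 were set before their values were seen, although the reading of the latter was tightened afterwards.

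Several gene groups did not pass. In all cells, S phase (28 of 38 positive, camera adjusted p = 0.0616) and G2 and M phase genes (38 of 51 positive, adjusted p = 0.0659) missed the threshold, as did immediate early genes (0.0616), excitatory differentiation (0.0554), astrocyte and oligodendrocyte precursor genes (0.0554), striatal and thalamic (0.0773), erythroid (0.0775), radial glia (0.0886), GABAergic (0.177), subplate and Cajal-Retzius (0.223) and vascular genes (0.267). The adjusted p was 0.583 for Polycomb machinery, 0.608 for Wnt signalling and for neurodevelopmental disorder genes, 0.622 for neurotrophin signalling, axon guidance, cholesterol synthesis and p53 targets, 0.650 for hypoxia and glycolysis, 0.711 for H3K36 and H3K4 methylation machinery, 0.736 for microglia, 0.782 for intermediate progenitor genes and 0.968 for mitochondrially encoded genes. For intermediate progenitor, microglia and mitochondrially encoded genes the mean fold change was above 0 while camera's direction was down. The Hox and the X-inactivation and Y-linked lists had too few measured members.

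Some members passed adjusted over the list alone and not over all genes. Gadd45g, of the growth arrest and DNA damage family, was 1.497-fold lower in glutamatergic neurons and 1.64-fold lower in upper-layer neurons, where the proneural factor gene Neurog2 was 1.58-fold and the growth cone protein gene Gap43 1.47-fold lower. The guidance ligand gene Sema3c was 1.53-fold higher in upper-layer neurons, and the adhesion gene L1cam 1.46-fold higher in deep-layer neurons. Fosb was 1.55-fold higher in all cells, 2.01-fold in deep-layer neurons and 1.93-fold in dorsal progenitors. In interneurons the ephrin receptor gene Ephb2 was 1.74-fold higher and Epha7 1.88-fold lower.

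Each count was set against the other splits of the 7 embryos into 4 and 3. In interneurons 1 of 35 splits, the real one with 6 genes, 4 of them haemoglobins, gave as many (highest other 4). That is the smallest share that 35 splits allow, and no allowance was made for the other counts tested this way. It therefore does not exclude chance. The count fell to 0 by edgeR at Leiden resolution 0.6 and with a minimum of 300 detected genes (635 and 598 at an unadjusted p under 0.05), and was 1 with DESeq2, 6 with voom and 1 without control 15. Nor was chance excluded elsewhere. As many genes came from 4 of 35 splits in all cells (3 genes, highest other 97), 3 in glutamatergic neurons (11, highest other 106) and 4 in upper-layer neurons (5, highest other 27). The number of splits was 2 in deep-layer neurons (7, highest other 13), 6 in dorsal progenitors (3, highest other 5) and 4 in the comparison of classes (5, highest other 8). The splits with 97, 106 and 27 genes set mutant 17 with the 3 controls and called several times the real count, which points to a structure of the samples. For lists, 20 splits gave as many in all cells (7 lists, highest other 17), 27 in glutamatergic neurons (2, highest other 7), 30 in upper-layer neurons (1, highest other 7), 11 in deep-layer neurons (2, highest other 4), 27 in progenitors (2, highest other 9) and 6 in interneurons (3, highest other 8).

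Esr1 was higher in mutants, and transcripts of the CreERT2 allele counted as Esr1 are a candidate explanation. Over 17 clusters of mutant cells the Esr1 level rose with that of Emx1 (Spearman rho 0.836, permutation p = 5.0e-05; Pearson r 0.749, permutation p = 2.2e-04; r 0.790 and rho 0.850 without the 2 farthest clusters). Mutant cells of the dorsal lineage held 142 Esr1 UMIs (12.1 CPM), and mutant interneurons and striatal neurons held 3 (1.70 CPM). Deep-layer cluster 10 did not follow, with 2.63 CPM of Esr1 in mutants and 6.15 CPM in controls (2 and 7 UMIs) at 65.8 CPM of Emx1 in mutants. Nor did the unnamed cluster 6, with 2.45 and 3.05 CPM (3 UMIs in each group) at 61.2 CPM of Emx1. Clusters 18 and 21 had too few mutant cells to be among the 17. The unnamed cluster 18, which has interneuron markers and may hold doublets, had 19.9 CPM (6 UMIs) at 56.3 CPM of Emx1. In interneuron clusters 9 and 11 Emx1 was at 5.22 and 25.1 CPM in mutants. The endothelial cluster 21 had 17.3 CPM (2 UMIs) at 95.3 CPM of Emx1. Clusters of the same embryos are not independent samples, and a rise of endogenous Esr1 in the Emx1 lineage would show the same pattern and was not separated.

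Spr was higher in mutants and lies 49.7 kb from Emx1. A loss of Ash1l acting within the recombined lineage alone would leave interneurons at 0. There the log2 fold change was 1.19 (normal 95% interval 0.31 to 2.07, edgeR adjusted p = 0.583). The class difference was 0.09 (SE 0.46, edgeR adjusted p = 0.995). Spr UMIs carried over from other cells were not excluded. Nor do the counts show that interneurons were unrecombined. Ash1l had a log2 fold change of −0.28 there and a class difference of −0.15 (SE 0.16). A sequence difference around Emx1 carried with the CreERT2 allele may act on Spr: of 93 other genes within 10 Mb, 8.60% had p under 0.05 in glutamatergic neurons (exact 95% interval 3.79% to 16.2%) against 11.6% of 10092 elsewhere (one-sided Fisher's exact p = 0.861). By the criterion set beforehand, that result argued against the explanation. It is left open because the interval includes the other share and an effect limited to the nearest genes would not show in the window. Npy, Lmcd1 and Lmo3, which passed in glutamatergic neurons, also lie on chromosome 6, outside that window (starts at 49822710, 112273758 and 138362918). Whether a sequence difference carried with the CreERT2 allele reaches them was not tested.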
